A study of Bos grunniens and Bos grunniens x Bos taurus with 6 samples.

How the data were processed

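RNA of single cells was measured with 10x Genomics libraries from testis of yak and of 1 cattle-yak. Per the labels' protocol, frozen tissue was thawed, digested with collagenase IV and hyaluronidase and then with trypsin, filtered through screens, resuspended in medium and cultured before loading. The labels carry the tag "Germ cell" as a cell line, although the tissue is given as testis and the cells held many somatic classes. Groups were taken from the labels: prepubertal yak of 6 months (replicates 1 and 2), adolescent yak of 18 months (replicates 3 and 4), a yak of 4 years after sexual maturity (replicate 5) and a cattle-yak after sexual maturity.

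The deposited matrices held raw UMI counts per gene and barcode, made with Cell Ranger and not normalised. The version was 5.0.0 per the file headers and 2.1.1 per the submitters' processing notes. The files named 26961 features, of which 15722 carried a symbol, 11239 only an identifier, and 37 were mitochondrial. The genome build is not given in the sources used here, and 0 identifiers matched the reference table, so symbols are those of the files and positions are not reported. The lowest barcode total was 500 UMIs in every library, so barcodes below that were not analysed here. Libraries shared between 5 and 16 barcodes, so no library was a copy of another. Among genes measured in both libraries of a pair, counts differed by a chi-square per degree of freedom of 63.6 between replicates 1 and 2 (12440 genes, r = 0.963) and of 242 between replicates 3 and 4 (15558 genes, r = 0.942), far above counting error.

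Totals were 19254307 and 15565708 UMIs at 6 months, 24762829 and 17482769 at 18 months, 15897418 at 4 years and 9575446 in the cattle-yak. Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept. The threshold of Scrublet itself marked 269 and 181 barcodes at 6 months, 1 in replicate 3 and 0 in the others. Doublets were therefore removed by rank of the Scrublet score (expected rate 0.06), at 0.8% per 1000 barcodes, which took 640, 367, 434, 305, 305 and 208 barcodes in the order of the libraries above. Of 40564 barcodes, 29243 cells were kept. Median depth per kept cell was 1722.5 and 1959 UMIs at 6 months, 1881 and 2074 at 18 months, 1480.0 at 4 years and 1467 in the cattle-yak.

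Cells were clustered together in scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9) with 10000 UMIs per cell as the target, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 2 with seed 0. No correction between libraries was made, so several classes were held by different clusters in different libraries. Such clusters are named beside many of the values but not beside all. A cluster was named from 13 marker lists fixed before the data were examined. A marker counted as raised at 2-fold the median CPM of the other clusters, with 10 CPM added to each side, and in at least 2% of cells. A name was refused where the 10 top genes held more markers of another class. It was also refused where UMIs were low and no marker of the class was among those genes. A name needed at least 3 raised markers, at least 0.333 of those in the files, and a lead over the next list of 0.5 in mean log2 fold or of 0.2 in the share of markers. Names carry "-like" because they rest on RNA alone, and a cluster held by 1 library of a group may be that library and not a type.

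Counts were summed per library and class, since cells are not replicates. A class was tested between 6 and 18 months where each of the 4 libraries held at least 50 of its cells. Genes were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with TMM normalisation and filterByExpr, at a Benjamini-Hochberg adjusted p below 0.05 within a class. The same test was run on sums over whole libraries. Lists of at least 5 measured members were tested with camera of limma 3.58.1 on log-CPM (prior count 2) with a preset correlation of 0.01 and with an estimated correlation beside it. The 18 lists fixed before the data were examined were steroid synthesis, cholesterol synthesis, the immature and the mature Sertoli state, cell cycle, collagen and matrix, IGF and insulin, mitochondrial electron transport, glycolysis, dissociation and stress response, Notch and hedgehog signalling, TGF-beta with activin and BMP, retinoid metabolism, interferon response, antigen presentation, meiosis, piRNA with transposon silencing, and sperm head, tail and chromatin. A gene was marked as possible free RNA where its CPM in a class lay under 20% of that in the class with the highest CPM (classes of at least 20 cells).

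The test was tried on simulated data with 200 changed genes in 5 simulations per class. It recovered between 0.6% and 6.6% of 2-fold changes and between 27.4% and 65.6% of 4-fold changes, and between 2.10% and 4.72% of its calls were false. A list of 20 genes shifted by 1 (log2) was called in 5 of 5 simulations, and 0 of 80 lists without a shift were. A gene outside the calls may thus have changed by 2-fold or more.

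The yak of 4 years against 18 months, and the cattle-yak against the yak of 4 years, hold 1 library on at least 1 side, so no test was made. Ratios of CPM by library total used a pseudocount of 1 CPM for ranking. Printed folds are plain ratios with exact intervals from the counts, for counting error only. Where one side had 0 counts, 3 counts of that library were used as its limit. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn within 20 bins of expression from genes with at least 10 counts, and lay outside the range below percentile 2.5 or above 97.5 against each library. In simulated data, lists of 12 genes shifted by 1 (log2) lay outside in 14 to 20 of 20 draws and lists without a shift in 0 to 4 of 20. Shares carry exact 95% Clopper-Pearson intervals, and a share of 0 is given with the limit of 3 counts of the total instead.

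Named genes followed a rule fixed before the data were examined. In each tested class these were the 6 largest rises and the 6 largest falls with an adjusted p below 0.05, a symbol, a mean of at least 50 CPM in the higher group, no overlap of libraries between the ages, and at least 20% of the CPM of the highest other class. Both libraries of 18 months thus lay on the same side of both of 6 months for each of them. Up to 4 members of each called list were added. Without a test, these were the 6 highest and 6 lowest ratios (to the nearer library of 18 months) with at least 50 counts and 50 CPM, a ratio of at least 2 and the same 20% limit, and up to 4 members of each list outside the range. The text prints a part of these, chosen for a known function, and some genes are not reported here. Markers are named where a class is described, and other genes are said to be chosen after their values were seen.

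Alternatives were the DESeq2 1.42.0 Wald test, size factors as DESeq2 makes them, no filter on low counts, each library of 6 and 18 months left out in turn, doublets kept, cells with at least 800 genes and at most 10% mitochondrial UMIs, Leiden resolution 4, all libraries in the fit, genes of possible free RNA left out, a pseudocount of 10 CPM and TMM-scaled CPM. Cells of up to 40% mitochondrial UMIs, the test without mitochondrial features, and library totals in place of TMM were added after the data were seen.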

Results

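Single-cell RNA libraries of testis were compared between yaks (Bos grunniens) of different ages and a cattle-yak, the hybrid of domestic cattle and yak, whose males are known to be sterile. The series asks how the fate of testis cells changes while the organ develops. Per the labels, 2 libraries came from prepubertal yaks of 6 months (replicates 1 and 2), 2 from adolescent yaks of 18 months (replicates 3 and 4), 1 from a sexually mature yak of 4 years (replicate 5) and 1 from a sexually mature cattle-yak. The libraries held between 5104 and 8946 barcodes, and between 9575446 UMIs (cattle-yak) and 24762829 UMIs (18 months, replicate 3). After filtering, 7396 and 5670 cells remained at 6 months, 3978 and 3994 at 18 months, 4563 at 4 years and 3642 in the cattle-yak, with a median of 1467 to 2074 UMIs per cell. The mitochondrial filter removed 2.30% and 3.56% of the barcodes with enough genes at 6 months, 38.0% and 20.3% at 18 months, 17.9% at 4 years and 14.1% in the cattle-yak. The labels do not say that the libraries of an age came from separate animals, so p-values measure only the spread between these samples. All intervals are 95% intervals and cover counting error only.

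Clustering gave 40 clusters, of which 35 were named into 10 classes by fixed markers. Sertoli-like cells, the nurse cells of the seminiferous tubule, carried the follicle-stimulating hormone receptor FSHR and INHA, with SOX9 in all clusters but 3 and 37. Their clusters had 4 or 5 of the 12 Sertoli markers raised. Stroma-like cells carried DCN and PDGFRA, with LUM raised only in the clusters that held the class at 6 months. Endothelial-like cells carried PECAM1 and CDH5, with VWF in all clusters but 28. Mural-like cells (peritubular myoid cells and vascular smooth muscle) carried ACTA2, MYH11 and TAGLN. Lymphocyte-like cells carried CD3D and NKG7, with CD52 in clusters 6, 9 and 35. Macrophage-like cells carried CD68, CD163 and C1QA, and the few Leydig-like cells CYP11A1 and STAR of steroid synthesis. Spermatogonium-like cells carried UCHL1, ZBTB16 and DMRT1, spermatocyte-like cells the meiotic genes SYCP1, SYCP2 and DMC1, and spermatid-like cells the acrosome genes ACRV1, SPACA1 and SPACA4. The other 5 clusters, with 777 cells, stayed unnamed.

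Sertoli-like and stroma-like cells made up most of the prepubertal libraries, and germ cells and endothelial-like cells held larger shares in the older libraries. Sertoli-like cells were 32.4% (31.3–33.5) and 33.3% (32.1–34.5) of cells at 6 months, and 2.34% (1.89–2.86) and 26.0% (24.6–27.4) at 18 months, a gap between replicates far above counting error. With cells of up to 40% mitochondrial UMIs, an alternative chosen after the data were seen, the share in replicate 3 was 5.10% (4.55–5.69). Only 2 such cells were seen at 4 years (0.0438%, 0.00531–0.158) and 5 in the cattle-yak (0.137%, 0.0446–0.320). These counts rest on the naming rule, since cluster 29, which it left unnamed, held 68 cells at 4 years and 312 in the cattle-yak with the Sertoli marker INHA at 1167 and 824 CPM. Unnamed cluster 38, with 76 cells of replicate 3, likewise held SOX9 at 1690 CPM and INHA at 880.1 CPM. Stroma-like cells were the largest class at 6 months, with 57.7% (56.5–58.8) and 42.9% (41.6–44.2). They were 41.5% (40.0–43.1) and 30.7% (29.2–32.1) at 18 months, 4.67% (4.07–5.32) at 4 years and 18.6% (17.4–19.9) in the cattle-yak. Endothelial-like cells were 2.95% (2.57–3.36) and 3.12% (2.68–3.61) at 6 months, 18.05% (16.9–19.3) and 16.2% (15.1–17.4) at 18 months, 33.0% (31.7–34.4) at 4 years and 15.7% (14.5–16.9) in the cattle-yak. Lymphocyte-like cells were 36.6% (35.0–38.2) of the cattle-yak library, 18.1% (17.0–19.3) of that of 4 years and 2.95% (2.57–3.36) to 14.8% (13.8–15.7) of the younger yak libraries. Mural-like cells were 9.77% (8.83–10.8) in the cattle-yak and between 1.91% (1.61–2.24) and 3.70% (3.13–4.33) in the yak libraries. Leydig-like cells, the source of testosterone, numbered 38 and 5 at 6 months, 6 at 4 years, and 0 in both libraries of 18 months and in the cattle-yak, which allows shares of up to 0.0754%, 0.0751% and 0.0824%. At 2 times the resolution there were 10 and 4 at 18 months and 1 in the cattle-yak, and with cells of up to 40% mitochondrial UMIs 21 in replicate 4 and 3 in the cattle-yak. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, so shares were not tested between ages. Every barcode held at least 500 UMIs and the tissue was digested and passed through fine screens, so the shares describe cells that passed these steps.

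**Figure D1:**
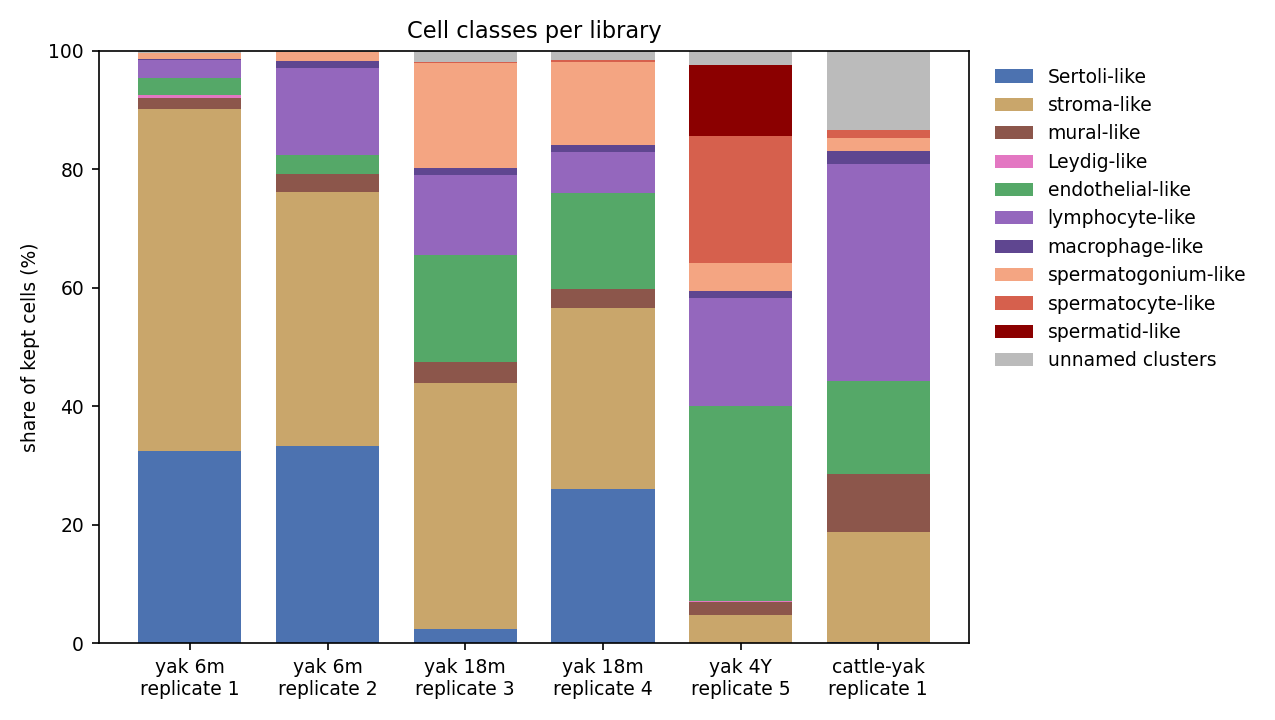
Stacked bars give the share of kept cells (%) in each named class and in unnamed clusters, one bar per library. Sertoli-like cells held 32.4% and 33.3% at 6 months, 2.34% and 26.0% at 18 months and 0.0438% at 4 years, and spermatid-like cells 11.9% at 4 years only.

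Germ cells reached the spermatid stage in the yak of 4 years and were not seen past the spermatocyte stage in the other 5 libraries. Germ cells were 0.960% (0.7505–1.21) and 1.43% (1.14–1.77) of cells at 6 months, 17.8% (16.7–19.1) and 14.3% (13.3–15.5) at 18 months, 38.2% (36.8–39.6) at 4 years and 3.43% (2.86–4.08) in the cattle-yak. At 6 months all 71 and 81 germ cells were spermatogonium-like, and at 18 months 99.6% (98.8–99.9) of 710 and 97.2% (95.5–98.4) of 573 were, with 3 and 16 spermatocyte-like cells. At 4 years 12.4% (10.9–14.1) of 1743 germ cells were spermatogonium-like, 56.3% (53.9–58.6) spermatocyte-like and 31.3% (29.1–33.5) spermatid-like. In the cattle-yak 60.8% (51.7–69.4) of 125 germ cells were spermatogonium-like and 39.2% (30.6–48.3) spermatocyte-like, and 0 were spermatid-like, which allows a share of up to 2.4%. The limits for spermatids were 4.23% and 3.70% at 6 months and 0.423% and 0.524% at 18 months. Spermatocyte-like cells lay in clusters 20 and 26. Cluster 20, whose next list was elongating spermatids, held 614 cells at 4 years and 1 in the cattle-yak. Cluster 26, with SPO11 and SYCP3 also raised, held 367 and 48, and 3 and 16 at 18 months. The spermatocyte-like shares at 4 years and in the cattle-yak thus join clusters that these libraries held unequally. With doublets kept, the spermatid-like share at 4 years was 49.3%, and 1 of 126 germ cells of the cattle-yak was spermatid-like (0.794%, 0.0201–4.34). With the stricter cell filter the spermatocyte-like share was 62.8% in the cattle-yak and 4.60% in replicate 4.

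**Figure D2:**
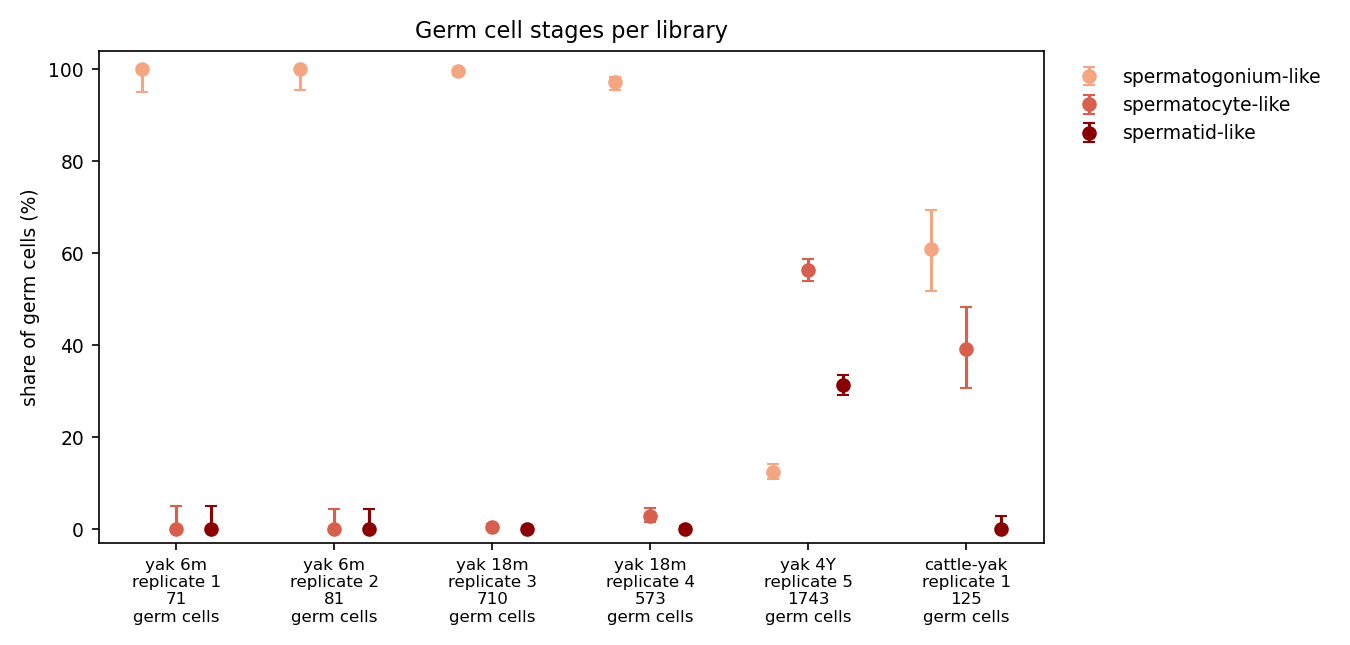
Points give the share (%) of spermatogonium-like, spermatocyte-like and spermatid-like cells among the germ cells of each library, with exact 95% binomial intervals as bars. Spermatid-like cells were 31.3% of germ cells at 4 years and 0 of 125 in the cattle-yak.

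Between 6 and 18 months, the germ cell genes DMRT1, SMC1B, SYCP1 and MAEL rose and the matrix genes DCN and COL5A1 fell in counts summed over whole libraries, which mix cell composition with expression. No gene list was tested on whole libraries. CPM are per library total, while fold changes are relative to the TMM scale, on which a ratio of 18 over 6 months lies below that of CPM by 1.03 (log2) in whole libraries, 0.93 in Sertoli-like, 0.40 in stroma-like, 0.29 in spermatogonium-like, 0.10 in endothelial-like, 0.06 in lymphocyte-like and 0.05 in mural-like cells. DMRT1 of spermatogonia rose by 3.20 ± 0.36 (log2 fold change ± SE, n = 2 libraries per age here and in each class, edgeR quasi-likelihood), from a mean of 5.40 CPM to 116 and 85.7 CPM. The meiotic cohesin SMC1B rose by 3.58 ± 0.37, SYCP1 of the synaptonemal complex by 3.66 ± 0.50, MAEL of transposon silencing by 3.45 ± 0.36 and the transketolase-like TKTL1 by 3.85 ± 0.47 (adjusted p = 0.0340, 0.0354, 0.0340 and 0.0340, edgeR quasi-likelihood with Benjamini-Hochberg adjustment; 0.0340 for DMRT1). The growth factor binding protein IGFBP3 fell by 3.65 ± 0.54, from 185 to 28.0 CPM, and the matrix genes DCN and COL5A1 fell by 2.88 ± 0.52 and 2.65 ± 0.44 (adjusted p = 0.0370, 0.0470 and 0.0425, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). These 8 genes were chosen after their values were seen. Of 13553 genes tested, 252 rose and 97 fell, among them 81 and 20 without a symbol. By library totals without TMM, an alternative chosen after the data were seen here and in each class, 2956 rose and 87 fell. The count of 349 was 44 without replicate 1 and 2401 without replicate 4, and edgeR called 0 genes without replicate 2 or without replicate 3, where 2088 and 2273 genes had an unadjusted p below 0.05 and no other tool was run. It was 1356 by DESeq2, 2206 without the filter on low counts and 0 with the stricter cell filter, where 2352 genes had an unadjusted p below 0.05.

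In Sertoli-like cells, transcripts of the mitochondrial genome rose between 6 and 18 months, as did the cationic amino acid transporter SLC7A3 and the secreted metalloprotease ADAMTS1. The metalloprotease inhibitor TIMP2 and the endoplasmic reticulum gene ERP27 fell. The depth of the class differed by age, with medians of 2663 and 2316 UMIs and 528 and 542 genes per cell at 6 months against 8339 and 5526 UMIs and 1722 and 1275.5 genes at 18 months. SLC7A3 (ENSBGRG00000007140) rose by 5.08 ± 0.76, from a mean of 1.02 to 70.2 CPM, and ADAMTS1 (ENSBGRG00000000068) by 3.67 ± 0.51, from 3.94 to 100.9 CPM (adjusted p = 0.0220 and 0.0143, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). ND2, ND3, ND6 and ND1, subunits of respiratory complex I, rose by 3.68 ± 0.57, 3.57 ± 0.63, 3.47 ± 0.68 and 3.11 ± 0.47 (adjusted p = 0.0220, 0.0332, 0.0386 and 0.0220, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The mitochondrial share of the class's UMIs was 1.11% ± 0.0486 (SD, n = 2) at 6 months and 12.5% ± 4.07 (SD, n = 2) at 18 months. Between clusters this share went with depth per cell. Clusters 1 and 33, almost all from 6 months, had medians of 0.253% and 5.31% at 2937 and 7946.5 UMIs. Clusters 37 and 11, mostly of replicate 4, had medians of 1.55% and 10.3% at 3032 and 6094 UMIs. TIMP2 (ENSBGRG00000019564) fell by 2.12 ± 0.41, or 1.21 by library totals, from 23109 to 9984 CPM (adjusted p = 0.0379, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). ERP27, PLA2G7, EXOC3L2, ECI1 and KDELR3 fell by 3.29 ± 0.55, 2.70 ± 0.53, 2.54 ± 0.45, 2.29 ± 0.45 and 2.16 ± 0.44 (adjusted p = 0.0274, 0.0386, 0.0332, 0.0386 and 0.0407, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and KDELR3 did not pass by library totals (−1.23, adjusted p = 0.0572, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Retinoid metabolism genes were lower as a list (camera, 10 members, median log2 fold change −1.04, or −0.19 by library totals, adjusted p = 0.0136, and adjusted p = 0.724 with an estimated correlation). Of these, 0 rose, 1 fell and 9 did not pass, and 4 fell adjusted over the list alone. The retinoic acid hydroxylase CYP26A1 fell (adjusted p = 0.0324, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), with 3 counts at 18 months and a ratio of 21.8 (7.31–107), and the retinol carrier gene RBP4 had −2.24, or −1.26 by library totals. Dissociation and stress genes were higher as a list (14 members, median 1.23, camera adjusted p = 0.00102, and adjusted p = 0.724 with an estimated correlation), 1 rose, 0 fell and 13 did not pass, with 4 rises adjusted over the list alone. The member that rose was ZFP36 (2.41 ± 0.46, adjusted p = 0.0336, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), at under 20% of its level in macrophage-like cells, and JUNB and JUN had 1.53 and 1.48. Nuclear genes of mitochondrial electron transport were lower than other genes as a list (10 members, median −0.86, camera adjusted p = 0.0136, and adjusted p = 0.724 with an estimated correlation), with 0 rising, 0 falling and 0 either way adjusted over the list alone. By library totals their median was 0.04. Of 8727 genes, 68 rose, 14 of them mitochondrial, and 54 fell, against 1773 and 51 by library totals. Clusters 1 and 3 held most of the class at 6 months and clusters 11 and 37 at 18 months, and the count of 122 was 6 without replicate 1, 812 without replicate 3 and 739 without replicate 4. Camera called 7 lists without replicate 3, against 3.

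In spermatogonium-like cells, transcripts of the mitochondrial genome rose along with the A-kinase anchoring genes AKAP12 and AKAP11 and the deubiquitinase USP9X, while STMN2 and the neuropeptide gene NPY fell. ND3 and ND2 rose by 4.27 ± 0.56 and 3.16 ± 0.52, from 33.2 to 802 CPM and from 165 to 1831 CPM (adjusted p = 5.97e-09 and 1.33e-05, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The mitochondrial share of the class's UMIs was 0.816% ± 0.208 (SD, n = 2) at 6 months and 6.26% ± 1.94 (SD, n = 2) at 18 months. AKAP12 (ENSBGRG00000006364) rose by 3.19 ± 0.61, from 15.1 to 170 CPM, and AKAP11 by 3.08 ± 0.71 (adjusted p = 0.000268 and 0.00507, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). WDR76 and USP9X rose from 2 counts each at 6 months, with ratios of 19.6 (5.40–162) and 22.7 (6.28–188) and adjusted p = 0.000283 and 0.000665 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). STMN2 (ENSBGRG00000017859) fell by 2.23 ± 0.46, from 291 to 74.0 CPM, NPY by 2.59 ± 0.53 and the kinase gene NEK8 by 2.71 ± 0.51 (adjusted p = 0.000774, 0.000871 and 0.000179, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). LYPD6B, IL18BP and DUSP23 fell by 2.38 ± 0.51, 2.33 ± 0.52 and 2.24 ± 0.50 (adjusted p = 0.00207, 0.00295 and 0.00279, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). None of the 16 lists measured was called (lowest camera adjusted p = 0.0820, with Benjamini-Hochberg adjustment). Sertoli markers were lower as a list in this class (7 members, median −1.07, camera adjusted p = 0.0193, and adjusted p = 0.404 with an estimated correlation), with 0 rising, 2 falling and 4 falling adjusted over the list alone, among them INHA, at under 20% of its level in Sertoli-like cells. INHA had 161 and 1192 CPM at 6 months and 85.1 and 179 CPM at 18 months, so the ages overlap. Of 8874 genes, 134 rose, 13 of them mitochondrial, and 102 fell, against 412 and 57 by library totals. Clusters 7 and 24 held the class at both ages. At 2 times the resolution, a cluster with a median mitochondrial share of 0.840% held 55 of 72 and 73 of 83 spermatogonium-like cells at 6 months but 207 of 707 and 187 of 557 at 18 months, and most others at 18 months lay in clusters with medians of 4.46% and 6.41%. In the test above, the count of 236 was 49 without replicate 1, 17 without replicate 2 and 966 without replicate 4.

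In stroma-like cells, the retinoic acid hydroxylase CYP26B1, the ephrin receptor EPHA3, the lipocalin APOD and the matrix gene FBLN2 rose from 6 to 18 months, and IGFBP5, the proteoglycan LUM and the neuropeptide precursor TAC1 fell. CYP26B1 (ENSBGRG00000014376) rose by 5.26 ± 0.68, from a mean of 1.69 CPM to 154 and 30.2 CPM in the libraries of 18 months, EPHA3 by 2.77 ± 0.38, APOD by 2.51 ± 0.45 and FBLN2 by 3.05 ± 0.48 (adjusted p = 0.00785, 0.00986, 0.0339 and 0.0210, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The keratin KRT18 and the growth arrest gene GAS6 rose by 3.44 ± 0.57 and 2.18 ± 0.40 (adjusted p = 0.0251 and 0.0401, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). IGFBP5 (ENSBGRG00000002228) fell by 3.98 ± 0.43, from 119 to 9.99 CPM, the chemokine CXCL11 by 4.19 ± 0.47, LUM by 3.34 ± 0.43, TAC1 by 3.03 ± 0.39 and the galanin receptor GALR1 by 2.82 ± 0.41 (adjusted p = 0.00521, 0.00521, 0.00785, 0.00785 and 0.0142, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Cholesterol synthesis genes were lower as a list (14 members, median −1.08, camera adjusted p = 4.04e-06, and adjusted p = 0.485 with an estimated correlation), with 0 rising, 0 falling and 5 falling adjusted over the list alone, and FDPS and CYP51A1 at −1.48 and −1.40, both at under 20% of their level in Leydig-like cells. Mitochondrial electron transport genes were lower (10 members, median −0.61, camera adjusted p = 0.0225, and adjusted p = 0.546 with an estimated correlation), with 0 rising, 0 falling and 0 either way adjusted over the list alone, and CYC1 and NDUFB1 at −0.86 and −0.77. By library totals the medians of these lists were −0.64 and −0.27. Germ cell genes were higher in this somatic class as lists of piRNA genes (5 members, median 4.16, camera adjusted p = 4.04e-06, and adjusted p = 0.485 with an estimated correlation; 3 rose, 0 fell, 4 rose adjusted over the list alone) and of meiosis genes (8 members, median 1.05, camera adjusted p = 0.0150, and adjusted p = 0.545 with an estimated correlation; 1 rose, 0 fell, 4 rose and 1 fell adjusted over the list alone). MAEL rose by 4.16 ± 0.54, and GTSF1 and TDRD9, with 1 count each at 6 months, had ratios of 69.6 (11.4–2853) and 48.2 (7.61–2007), while SMC1B, with 2 counts, had 99.0 (26.5–833), all at under 20% of their level in spermatogonium-like cells (adjusted p = 0.00785, 0.0279, 0.0428 and 0.00725, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Spermatogonial markers were likewise higher in the class (6 members, median 2.45, camera adjusted p = 1.94e-07, and adjusted p = 0.122 with an estimated correlation; 3 rose, 5 adjusted over the list alone), as were mural markers (10 members, median 0.70, camera adjusted p = 0.00522, and adjusted p = 0.200 with an estimated correlation; 3 rose, 3 adjusted over the list alone). Of 9171 genes, 73 rose and 15 fell (110 and 11 by library totals), and 47 of the rises lay at under 20% of the level in another class. Clusters 2, 5, 8, 13, 14 and 27 held the class at 6 months, cluster 4 in replicate 3 and cluster 10 in replicate 4, and the count of 88 was 22 without replicate 3 and 957 without replicate 4. Camera called 1 list without replicate 3, against 4.

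In mural-like cells, CNN1, ACTA2 and MYH11 of smooth muscle rose from 6 to 18 months and the matrix gene POSTN fell. The class joined cluster 23, led by RGS5, and cluster 25, led by ACTA2, TPM2 and TAGLN. CNN1 was raised in cluster 25 but not in cluster 23. Cluster 25 held 22 of 141 and 6 of 168 cells at 6 months, and 118 of 147 and 62 of 125 at 18 months. A change in the mix of clusters and a change within cells were not told apart. CNN1 (ENSBGRG00000013580), an actin-binding calponin, rose by 6.37 ± 1.07, from 3 counts at 6 months (ratio 119, 40.4–580) to 730.3 and 42.0 CPM, and RERGL, NDRG4 and ID4 rose by 5.30 ± 0.74, 4.82 ± 0.76 and 3.24 ± 0.58 (adjusted p = 0.00336, 0.000928, 0.00159 and 0.00452, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). LTBP1, which binds latent TGF-beta, and SLMAP rose from 2 and 3 counts, with ratios of 25.9 (6.84–220) and 16.3 (5.28–81.8) and adjusted p = 0.0116 and 0.0174 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). POSTN (ENSBGRG00000021859) fell by 4.49 ± 0.69, from 213 to 10.8 CPM, UBA7 by 2.91 ± 0.63 and GALR1 by 2.36 ± 0.58 (adjusted p = 0.00159, 0.0229 and 0.0383, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The markers of the class were higher as a list (12 members, median 1.62, camera adjusted p = 3.96e-06, and adjusted p = 0.182 with an estimated correlation), and 5 rose, with 8 adjusted over the list alone. The smooth muscle actin ACTA2 rose from 1411 to 6207 CPM, and the myosin MYH11, the intermediate filament gene DES and TAGLN rose by 2.62 ± 0.61, 2.70 ± 0.59 and 1.55 ± 0.38 (adjusted p = 0.0191, 0.0355, 0.0254 and 0.0378, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Collagen and matrix genes were lower as a list (14 members, median −0.72, camera adjusted p = 4.03e-05, and adjusted p = 0.453 with an estimated correlation), with 0 rising and 1, POSTN, falling, also adjusted over the list alone, and COL5A1, COL4A1 and LAMC1 at −1.37, −1.36 and 1.47. TGF-beta, activin and BMP genes were higher (8 members, median 0.55, camera adjusted p = 0.00933, and adjusted p = 0.453 with an estimated correlation), with 0 rising, 0 falling and 3 rising adjusted over the list alone, and TGFB3 and ACVR2B at 2.67 and 2.19. Of 3441 genes, 39 rose and 10 fell, against 9 and 5 by library totals, where LTBP1, SLMAP, UBA7 and GALR1 did not pass. Cluster 23 held most of the class at 6 months and cluster 25 most in replicate 3, while replicate 4 had 63 and 62 cells in them, and the count of 49 was 9 without replicate 2, 13 without replicate 3 and 439 without replicate 4. Camera called 1 list without replicate 2, 3 or 4, against 2.

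In endothelial-like cells, few genes passed the test between 6 and 18 months. The orphan nuclear receptor NR4A1 (ENSBGRG00000000523) rose by 2.45 ± 0.43, from 15.7 to 90.5 CPM, the titin cap gene TCAP by 3.39 ± 0.50 and the glycerophosphocholine phosphodiesterase GPCPD1 by 2.09 ± 0.42, and NPY fell by 1.87 ± 0.42, from 145 to 44.3 CPM (adjusted p = 0.00561, 0.000555, 0.0198 and 0.0458, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Stress genes were higher as a list (14 members, median 0.58, camera adjusted p = 0.0113, and adjusted p = 0.492 with an estimated correlation), with ZFP36, JUNB and EGR1 at 1.23, 1.18 and 1.16. Cell cycle genes (7 members, median −0.57) and collagen and matrix genes (11 members, median −0.29) were lower, each with camera adjusted p = 0.0113, and adjusted p = 0.492 with an estimated correlation. The replication genes MCM3, MCM6 and MCM2 had −1.30, −1.10 and −1.03, and COL4A1 and LAMB1 −0.84 and −0.54, while DCN and COL5A1, at −1.50 and −1.37, lay under 20% of their stroma level. Libraries of the 2 ages overlapped for MCM3 and LAMB1. In each of these 3 lists 0 members rose and 0 fell, also adjusted over the list alone. Of 7198 genes, 18 rose and 9 fell, against 20 and 7 by library totals, where NPY did not pass. Clusters 12 and 18 held most of the class at 18 months, and the count of 27 was 59 without replicate 3 and 314 without replicate 4. Camera called 0 lists without replicate 4, against 3.

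In lymphocyte-like cells, 1 of 6124 genes rose and 3 fell (1 and 1 by library totals), none of them with a symbol in the files. ENSBGRG00000010827 fell by 4.83 ± 0.62, from 213 to 8.57 CPM, and ENSBGRG00000016463 by 2.92 ± 0.47, at under 20% of its level in Sertoli-like cells, while ENSBGRG00000025419 rose from 6.78 to 131 CPM, at under 20% of its level in spermatogonium-like cells (adjusted p = 0.00498, 0.0431 and 0.00494, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). These IDs were chosen after their values were seen. Cell cycle genes were lower as a list (17 members, median −0.67, camera adjusted p = 8.18e-06, and adjusted p = 0.623 with an estimated correlation), with 0 rising, 0 falling and 0 either way adjusted over the list alone, and the topoisomerase TOP2A and BIRC5 both at −1.46, with libraries of the 2 ages overlapping. With cells of up to 40% mitochondrial UMIs, an alternative chosen after the data were seen, TOP2A and BIRC5 were at 1.25 and 0.37. Collagen and matrix genes were lower too (7 members, median −1.89, camera adjusted p = 2.15e-06, and adjusted p = 0.623 with an estimated correlation), with 0 rising, 0 falling and 5 falling adjusted over the list alone, and DCN at −3.81, under 20% of its stroma level. Clusters 6 and 9 held most of the class. Cluster 35, led by the cycling genes CENPF and TOP2A, held 49 of 218 and 49 of 837 cells at 6 months, and 22 of 533 and 2 of 277 at 18 months. The 4 calls were 0 by edgeR without replicate 1, where 227 genes had an unadjusted p below 0.05 and no other tool was run, and 116 without replicate 2 or without replicate 4. Camera called 0 lists without replicate 1, against 2.

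**Figure D3:**
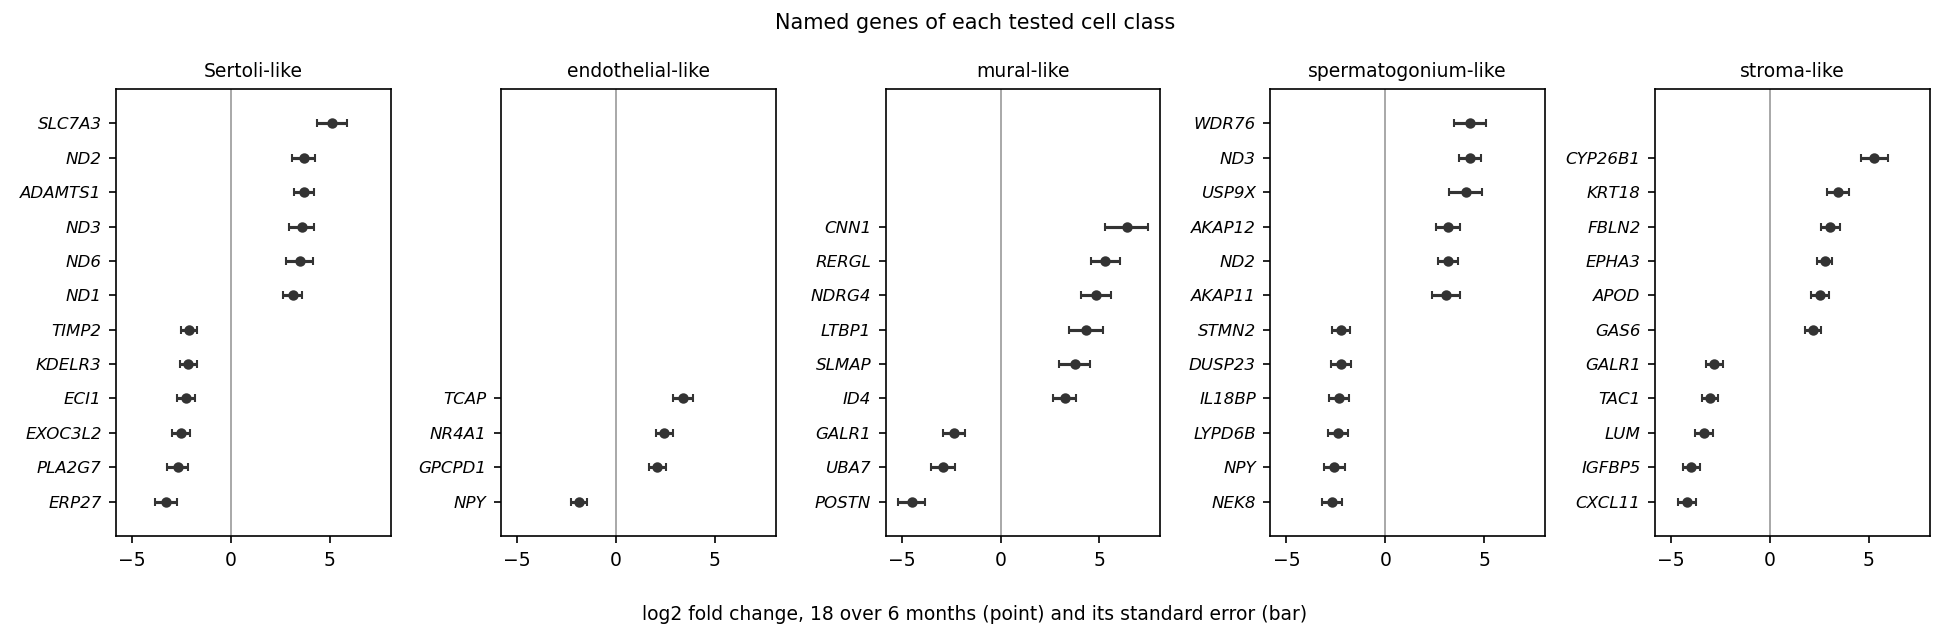
Points give the log2 fold change of 18 over 6 months for the named genes of each tested class, and bars give ± 1 SE from edgeR (2 against 2 libraries). Among the genes drawn, which leave out members of lists, CNN1 in mural-like cells had 6.37 and POSTN in mural-like cells −4.49.

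Several lists were called in no tested class. The lowest camera adjusted p was 0.0820 for steroid synthesis, for the immature Sertoli state, for glycolysis and for sperm head, tail and chromatin genes, 0.834 for the mature Sertoli state, 0.106 for IGF and insulin, 0.0865 for Notch and hedgehog signalling and 0.0816 for the interferon response. Antigen presentation had fewer than 5 measured members in each class. In all classes tested, the mitochondrial share of UMIs was higher at 18 than at 6 months, from 6.55% ± 0.297 to 13.5% ± 0.512 (SD, n = 2) in stroma-like cells, from 7.57% ± 0.178 to 13.2% ± 1.43 in mural-like cells, from 6.74% ± 0.407 to 10.3% ± 3.71 in lymphocyte-like cells and from 3.78% ± 0.868 to 6.25% ± 1.70 in endothelial-like cells.

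**Figure D4:**
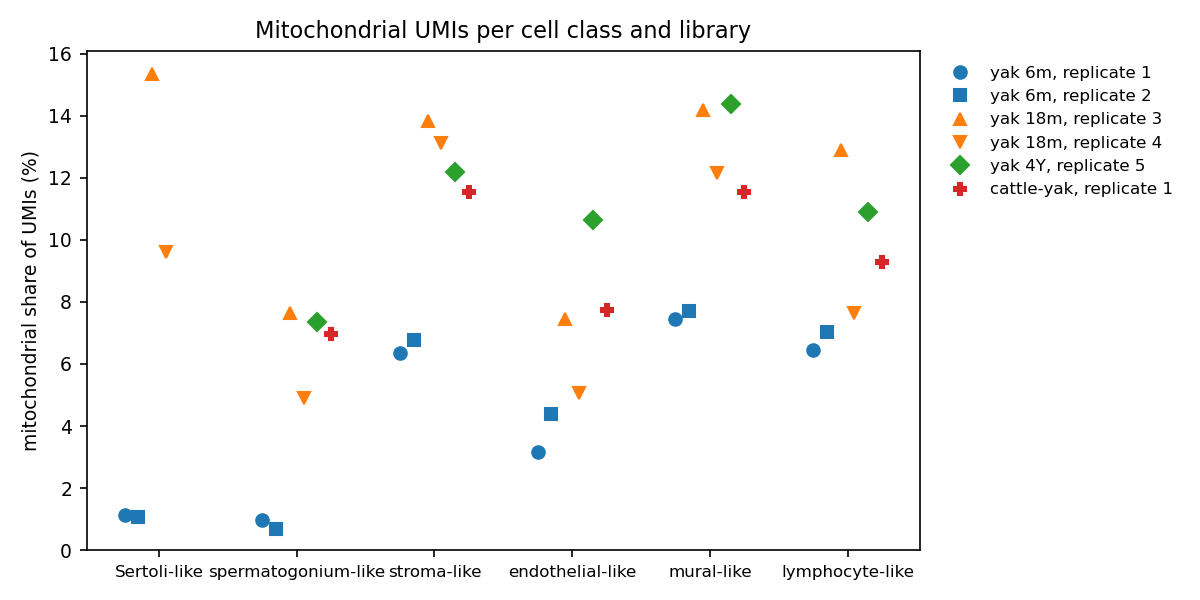
Points give the mitochondrial share of UMIs (%) summed over each class with at least 50 cells, per library. In Sertoli-like cells the mean was 1.11% at 6 months and 12.5% at 18 months.

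The yak of 4 years was compared with both adolescent libraries to ask what sexual maturity changes within a class. Endothelial-like and stroma-like cells of the mature library had lower levels of immediate early stress genes, and spermatogonium-like cells had lower levels of cell cycle genes. There was 1 library at 4 years, so no difference in this comparison has a replicate check and none was tested. Folds are given against the nearer library of 18 months, and percentiles place a list's median among 10000 random lists matched on expression, as a description of these libraries. In endothelial-like cells the stress genes had medians of −1.28 and −0.67 against replicates 3 and 4 (percentiles 0 and 0.01, 14 members), with DUSP1 at 793 CPM against 2840 and 2493 CPM and FOS at 1457 against 5437 and 3898 CPM. The endothelial multimerin MMRN1 (ENSBGRG00000022987) was 11.99-fold higher (9.10–16.1), at 291 against 0.558 and 24.3 CPM, the reelin gene RELN 11.4-fold higher (6.85–20.2). Both lead cluster 28, which held 290 cells at 4 years against 1 and 22 at 18 months. The laminin LAMA2 was 12.2-fold higher (7.12–22.3). The immunoproteasome gene PSMB8 was 4.88-fold lower (4.06–5.90) and the G protein gamma subunit gene GNG5 5.58-fold lower (4.14–7.64). Cell cycle genes had medians of 0.66 and 1.13 (percentiles 98.6 and 98.6, 17 members), with AURKA at 35.4 against 6.42 and 2.25 CPM, under 20% of its spermatocyte level, and genes of the immature Sertoli state −1.11 and −0.61 (percentiles 0.26 and 0.45, 6 members), with INHA at 7.74 against 59.1 and 157 CPM, under 20% of its level in Sertoli-like cells. Clusters 12 and 18 held most of the class at 18 months and clusters 16, 21 and 28 at 4 years.

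In stroma-like cells the stress genes had medians of −1.93 and −1.43 (percentiles 0 and 0, 14 members), with JUN 6.89-fold lower (6.25–7.62) and FOS 6.56-fold lower (5.55–7.80). Cholesterol synthesis genes had medians of 0.78 and 1.41 (percentiles 99.7 and 99.8, 14 members), with the sterol demethylase CYP51A1 3.95-fold higher (2.35–6.48), at under 20% of its spermatid level, and FDPS 3.48-fold higher (2.30–5.22). CYP11A1 (ENSBGRG00000004363), the first enzyme of steroid synthesis, was 37.0-fold higher (20.5–71.5), at 222 against 6.005 and 0.703 CPM. That lay under 20% of the 1170 CPM of Leydig-like cells at 6 months, a class with 6 cells at 4 years and 0 at 18 months. The calcium-binding gene S100A4 was 55.6-fold higher (40.3–78.5). STMN2 was 47.6-fold lower (23.0–119) and the homeobox gene SHOX2 7.27-fold lower (2.78–27.1). Mural markers in this class had medians of 1.75 and 3.67 (both at percentile 100), and cluster 15 held most of the 213 cells at 4 years while clusters 4 and 10 held most at 18 months.

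In spermatogonium-like cells, cell cycle genes had medians of −0.60 and −0.27 (percentiles 1.82 and 2.22, 18 members), with UBE2C 5.13-fold lower (2.17–15.95) and PCNA 2.37-fold lower (1.60–3.65). The mitochondrial ribosome gene MRPS24 was 8.68-fold lower (4.33–20.3), the fatty acid binding gene FABP5 4.55-fold lower (3.38–6.25), and YRDC 2.01-fold higher (1.85–2.18). Genes of the immature Sertoli state had medians of −1.29 and −0.81 (percentiles 0.35 and 0.29), with INHA 15.2-fold lower (6.47–46.9), likewise under 20% of its Sertoli level. In mural-like cells the metallothionein MT2A was 13.5-fold higher (10.9–17.0), at 4224 against 170 and 312 CPM, the skeletal actin ACTA1 6.06-fold higher (3.54–10.8), and the calcification inhibitor MGP 3.44-fold lower (3.05–3.89). In that class 0 of 11 lists lay outside the random range. In lymphocyte-like cells the surface gene CD48 was 5.94-fold lower (4.64–7.72) and PFN1, of actin assembly, 4.62-fold lower (3.97–5.41). CHURC1 was 3.99-fold higher (2.66–6.21). Cluster 19 held most lymphocyte-like cells at 4 years and clusters 6 and 9 at 18 months. Of spermatogonium-like cells, clusters 7 and 24 held 170 and 47 at 4 years. At 18 months they held 383 and 324 (replicate 3) and 445 and 112 (replicate 4). Of mural-like cells, clusters 23 and 25 held 35 and 65 at 4 years. At 18 months they held 29 and 118 (replicate 3) and 63 and 62 (replicate 4). The part of these mixes in the values above was not tested.

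Genes of meiosis and of sperm were higher at 4 years in somatic classes as well. Sperm head, tail and chromatin genes had medians of 4.01 and 4.06 in endothelial-like cells, 4.51 and 4.51 in lymphocyte-like cells, 5.55 and 5.12 in stroma-like cells and 1.28 and 1.21 in spermatogonium-like cells (percentiles from 99.99 to 100). With members at 0 counts set at their bound (3 counts per library), these were 4.10 and 3.81, 3.67 and 3.27, 5.15 and 4.91, and 1.28 and 1.21. Against replicate 3, HMGB4, a germ cell HMG-box gene, was at least 138-fold higher in endothelial-like and at least 139.7-fold higher in stroma-like cells. Replicate 4 held fewer UMIs in these classes (2222754 against 3584935, and 1423253 against 2331478), so the bounds against it are lower. Meiosis genes had medians of 1.99 and 2.28, 1.51 and 3.14, and 1.27 and 2.19 in endothelial-like, lymphocyte-like and stroma-like cells, and piRNA genes 1.67 and 2.53, 1.09 and 2.56, and 1.02 and 2.09 (percentiles from 99.5 to 100). With members at 0 counts set at their bound, the medians against replicate 4 were 2.23, 1.48 and 2.097 for meiosis genes and 2.22, 1.48 and 2.09 for piRNA genes. Round spermatid markers reached 250.3 CPM in stroma-like, 219.8 CPM in endothelial-like and 263 CPM in lymphocyte-like cells at 4 years, against 6308 CPM in spermatid-like cells. At least 1 such UMI was seen in 25.8% of stroma-like, 32.0% of endothelial-like and 32.9% of lymphocyte-like cells (median 1238, 1389 and 1405 UMIs), none of which should make them, and in 97.4% of spermatid-like cells (median 1435 UMIs).

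The cattle-yak was compared with the mature yak to ask how the testis of the sterile hybrid differs. Spermatogonium-like cells of the hybrid had higher levels of the protease inhibitor SLPI and of DMRT1, stroma-like cells had higher levels of APOD, of the complement gene C7 and of DCN, and macrophage-like cells had lower levels of the complement genes C1QA, C1QB and C1QC. Each side held 1 library, so there was no replicate check and no test, and the values compare these libraries and not the kinds of animal. In spermatogonium-like cells (76 and 217 cells) SLPI (ENSBGRG00000011283) was 6.23-fold higher (4.95–7.86), at 964 against 155 CPM, RADX, which binds single-stranded DNA, 3.57-fold higher (2.58–4.91) and DMRT1 (ENSBGRG00000003868) 2.24-fold higher (1.66–2.99), at 394 against 176 CPM. DMRT1 was at 240 and 347 CPM in the yak libraries of 18 months. Replicate 4 of the yak thus lay nearer to the hybrid than to the yak of 4 years. Cluster 24, of median 16467.5 UMIs, held 4 cells of the hybrid and 47 of the yak of 4 years, and cluster 7 held 72 and 170. Median depth was 861 and 1447 UMIs, with median mitochondrial shares of 9.17% and 6.56%. A change in this mix and a change within cells were not told apart. By the limits on counts, CPM and ratio, 15 genes were higher and 260 lower. The hybrid class held 175298 UMIs against 891628, so fewer of its genes could reach 50 counts. The metallothionein MT3 and the uroplakin UPK3A had 0 counts in the hybrid and were at least 4.19-fold and at least 4.13-fold lower, and the pyruvate dehydrogenase kinase PDK2, with 1 count, was 12.2-fold lower (2.11–489). Collagen and matrix genes had a median of 0.90 (percentile 99.3, 6 members), with DCN 4.58-fold higher (1.65–12.5), at 51.3 CPM and under 20% of its level in stroma-like cells. Markers of other classes were higher there as well, with OGN of stroma at 131 against 5.61 CPM, RGS5 of mural cells at 45.6 against 1.12 CPM and CCL5 of lymphocytes at 199.7 against 37.0 CPM. Spermatocyte markers had a median of 0.62 (percentile 99.6, 10 members). SYCP1 (245 against 253 CPM), TEX15 (137 against 237 CPM), CCNA1, MEIOB and SPO11 were lower in the hybrid, and the other markers higher. Apart from SYCP1 and TEX15, all lay at or under 91.3 CPM in the hybrid. With 175298 UMIs in the class, these values rest on few counts.

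In stroma-like cells (678 and 213 cells, most of them in cluster 15) APOD was 4.60-fold higher (3.99–5.33), C7 4.59-fold higher (2.88–7.75), STMN2 11.5-fold higher (5.50–28.9) and FGL1 5.33-fold higher (2.51–13.6). Collagen and matrix genes had a median of 0.53 (percentile 99.98, 18 members), with DCN 3.26-fold higher (2.71–3.96), at 1413 against 434 CPM. Cholesterol synthesis genes had a median of −1.71 (percentile 0.11, 9 members), with CYP51A1 11.01-fold lower (4.63–30.1), at under 20% of its spermatid level. The calmodulin CALM3 was 6.66-fold lower (5.60–7.93) and the small heat shock gene CRYAB 5.65-fold lower (3.93–8.21). Mural markers had a median of −1.54 (percentile 0.01, 11 members). In macrophage-like cells (85 and 55 cells) C1QA was 8.09-fold lower (6.73–9.75), at 624 against 5043 CPM, C1QC 8.10-fold lower (6.43–10.3) and C1QB 4.23-fold lower (3.47–5.18). The yak libraries themselves differed widely in these genes. At 18 months, replicates 3 and 4 had C1QA at 1174 and 5025 CPM, C1QB at 838 and 4443 CPM and C1QC at 743 and 4645 CPM. The chemokine CXCL10 was 4.65-fold higher (2.37–10.4), and the lamin LMNA, with 0 counts in the yak, at least 5.73-fold higher.

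In endothelial-like cells the apolipoprotein APOA1 was 7.03-fold higher (6.44–7.69), at 1550.4 against 220.5 CPM, and SFRP1, a secreted Wnt inhibitor, 26.4-fold higher (11.7–73.4), while NPY was 27.3-fold lower (11.5–85.1) and the nuclease DNASE1L3 7.54-fold lower (6.13–9.37). Clusters 16, 21 and 28 held most of that class in the yak and clusters 21 and 18 in the hybrid, with 734 and 26 cells in cluster 16. In mural-like cells MT2A was 4.79-fold lower (4.38–5.25), DEPP1 5.76-fold lower (4.41–7.53) and SERPINE2 5.17-fold higher (2.84–10.5). Collagen genes had a median of 0.43 (percentile 99.4). In lymphocyte-like cells, most of them in clusters 17 and 9 in the hybrid and in cluster 19 in the yak, the oxysterol receptor GPR183 was 5.53-fold higher (4.18–7.44), the retinoic acid binding gene CRABP1 16.01-fold higher (7.98–37.6), with a retinoid median of 0.63 (percentile 98.8). The squalene synthase FDFT1 was 5.20-fold lower (3.33–8.35), with a cholesterol median of −0.75 (percentile 1.72). In simulated data of this class and comparison, 4 of 20 lists without a shift lay outside the random range. Stress genes had medians of 0.78 in endothelial-like, 0.86 in macrophage-like, 0.43 in lymphocyte-like and 0.42 in stroma-like cells (percentiles from 99.6 to 100), with FOS 2.19-fold higher (2.099–2.28) in endothelial-like and 2.22-fold higher (1.86–2.67) in stroma-like cells. Collagen genes had medians of 0.31 in endothelial-like and 0.63 in lymphocyte-like cells (percentiles 99.7 and 99.8), where stroma markers had 1.73 and 2.76 (both at percentile 100), the latter 2.03 with members at 0 counts set at their bound. Cell cycle genes had a median of −1.28 in endothelial-like cells (percentile 0.32), with AURKA 21.9-fold lower (7.26–108), at under 20% of its spermatocyte level.

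Sperm genes were lower in the classes of the hybrid, with medians of −4.02 in endothelial-like, −4.51 in lymphocyte-like, −5.55 in stroma-like and −4.55 in spermatogonium-like cells (all at percentile 0), and of −3.63, −3.98, −4.21 and −0.93 with members at 0 counts set at their bound. CRISP2 was at least 118-fold lower in endothelial-like, at least 164-fold lower in lymphocyte-like and at least 7.41-fold lower in spermatogonium-like cells. Meiosis genes had medians of −2.25, −2.18, −1.78 and −2.84 in endothelial-like, lymphocyte-like, mural-like and stroma-like cells (percentiles from 0 to 0.12), and piRNA genes −3.07 and −3.75 in endothelial-like and lymphocyte-like cells (percentiles 0 and 0.02), or −2.19 and −3.75 with members at 0 counts set at their bound. Round spermatid markers had 1010 CPM over all barcodes of the mature yak and 3.55 CPM over those of the cattle-yak. The lists of steroid synthesis, the mature Sertoli state, IGF and insulin, electron transport, glycolysis, Notch and hedgehog, TGF-beta, interferon response and antigen presentation lay outside the random range in no class in either comparison without a test.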

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

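Of the tests below, those on the number of germ cells sampled, on the hybrid, on free mitochondrial RNA and on age were chosen after the result was seen.

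Spermatid-like cells were absent from 125 germ cells of the cattle-yak. Chance in sampling is argued against, since the upper limit of 2.4% lies under the lower limit of 29.1% in the yak of 4 years. Removal by the cell filters is argued against as well, since round spermatid markers in barcodes that failed the filters were at 0.00464 times the yak's level (upper limit 0.0119). The hybrid's sterility stays open and cannot be told apart from the single animal, its age or the handling, because there was 1 library of cattle-yak.

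Sperm genes such as HMGB4 and CRISP2 were seen in somatic classes of the yak of 4 years. Doublets with spermatids are argued against as the whole cause, since the 5% of somatic cells with most such UMIs held 28.8% of them, under the bound of 50 set before. Free RNA in every droplet fits, since that share was 0.946 times the 30.4% of Poisson draws. The higher sperm, meiosis and piRNA genes of somatic classes at 4 years, and their lower values in the hybrid, may therefore reflect how many spermatids and spermatocytes a library held. Other genes, such as AURKA and CYP51A1, were also marked as possible free RNA. In endothelial-like cells 150 of 203 higher genes at 4 years and 172 of 240 lower genes in the hybrid were so marked. In stroma-like cells 37 of 105 and 42 of 83 were. Their source was not tested.

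Mitochondrial transcripts, among them ND1, ND2 and ND3, were higher at 18 months in Sertoli-like cells. Free mitochondrial RNA in every droplet is argued against as the whole cause, since taking off the lowest share of another tested class in the same library, as the most it can add, left 7.91% in replicate 3 and 4.71% in replicate 4 (SD 2.26), against at most 1.15% at 6 months. The excess of the rise over that of the other classes decides nothing, at 4.45 points in all and 1.93 points without replicate 3, against an SD of 4.07. The filter at 20% is argued against, since at 10% the lowest share at 18 months was still 3.78 times the highest at 6 months. That lowest share, 3.65%, rests on only 24 of 93 cells of replicate 3, and cells were picked by the share itself. In replicate 4 the share was 6.92% in 568 of 1038 cells, against 0.967% and 0.861% at 6 months. Age stays open and cannot be told apart from tissue quality or handling, with a gap of 8.45 points between the lowest share at 18 months and the highest at 6 months, because each library has 1 age. Between clusters the share also went with depth per cell, as given above, and the part of depth in the rise was not tested.

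Some genes moved in opposite directions in 2 classes between 6 and 18 months, in both libraries of each age, and the difference itself was not tested. The lipocalin APOD fell by 4.33 in Sertoli-like cells and rose by 2.51 in stroma-like cells, a difference of −6.84. The dipeptidase DPEP1 fell by 4.04 in Sertoli-like and rose by 2.78 in stroma-like cells, a difference of −6.82. The chemokine CXCL9 rose by 3.98 in endothelial-like and fell by 2.13 in spermatogonium-like cells, a difference of 6.11, at under 20% of its macrophage level in both. The keratin KRT18 fell by 2.06 in spermatogonium-like and rose by 3.44 in stroma-like cells, a difference of −5.50. The growth cone gene GAP43 fell by 1.70 in spermatogonium-like cells and was at least 19.6-fold higher in stroma-like cells, where it had 0 counts at 6 months, so the fitted difference of −8.70 is no bound. IGFBP5 fell by 3.98 in stroma-like cells and rose in spermatogonium-like cells from 2 counts (ratio 7.46, 2.05–61.8), a fitted difference of 6.9965.

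Cluster 34, which no comparison used, held 144 cells in the cattle-yak, 3.95% of the library (3.34–4.64), against 7 in the yak of 4 years and 1 in replicate 4. Its leading symbols were WFDC2, TF, S100A2 and MT3, and PAX8 and KRT7 were raised, which was fewer than the 3 markers a name needed.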

How the results depend on the processing

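Of the tests below, cells of up to 40% mitochondrial UMIs, the test without mitochondrial features and library totals without TMM were chosen after the result was seen, and the others were chosen before the data were examined.

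Most named genes kept their direction between 6 and 18 months. Apart from members of lists, these genes were chosen to have no overlap between the ages, and the alternatives compared the same libraries. Kept direction was thus largely set by the choice of genes and is no independent check. Over all alternatives, 1258 results for named genes kept direction and side of the threshold, 109 no longer passed, 53 newly passed and 2 turned: TOP2A was at 1.25 and BIRC5 at 0.37 in lymphocyte-like cells with up to 40% mitochondrial UMIs. Results that kept their side include members of lists that had not passed. Only genes that had passed can stop passing, so the losses are a larger share of those genes than of all results. Most of the losses came with replicate 1 or replicate 2 left out. Without a test, 174 values of named genes at 4 years and 289 in the cattle-yak held within their interval, and 68 and 57 moved. The cause was not tested for the results that moved.

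Counts of genes moved more. By library totals without TMM, 3043 changed in whole libraries (2956 rose and 87 fell, against 252 and 97), 1824 in Sertoli-like (1773 and 51, against 68 and 54), 469 in spermatogonium-like (412 and 57, against 134 and 102), 14 in mural-like (9 and 5, against 39 and 10) and 2 in lymphocyte-like cells (1 and 1, against 1 and 3). The median fold change of all genes was then 1.03 in whole libraries and 0.97 in Sertoli-like cells (−0.04 and 0.07 with TMM), and 6 results for named genes that had passed no longer did. By DESeq2, 1356 genes changed in whole libraries (349 by edgeR), 525 in Sertoli-like (122) and 24 in lymphocyte-like cells (4). It called 27 in mural-like (49) and 125 in spermatogonium-like cells (236). Genes called by both tools were 349 in whole libraries, 87 in Sertoli-like, 4 in lymphocyte-like, 25 in mural-like and 110 in spermatogonium-like cells. Without the filter on low counts there were 2206 in whole libraries, 623 in Sertoli-like, 80 in endothelial-like (27), 107 in lymphocyte-like, 93 in mural-like, 148 in spermatogonium-like and 431 in stroma-like cells (88). With at least 800 genes and at most 10% mitochondrial UMIs, edgeR called 0 in whole libraries and 0 in lymphocyte-like cells, where 2352 and 137 genes had an unadjusted p below 0.05 and no other tool was run, and 13 in endothelial-like cells. That filter gave no value for Sertoli-like, mural-like, spermatogonium-like and stroma-like cells, where a library held fewer than 50 cells. With up to 40% mitochondrial UMIs there were 223 in Sertoli-like, 8 in lymphocyte-like and 48 in stroma-like cells. With all libraries in the fit there were 52 in endothelial-like, 87 in lymphocyte-like and 123 in mural-like cells. Without possible free RNA there were 16 in endothelial-like, 1 in lymphocyte-like, 25 in mural-like and 15 in stroma-like cells, where fewer genes were counted by construction. At 2 times the resolution there were 8 in lymphocyte-like and 22 in mural-like cells, with DESeq2 size factors 2 in lymphocyte-like cells, and with doublets kept 64 in spermatogonium-like cells.

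Leaving out 1 library left 1 in a group, assumed to vary like the other group. Counts ranged from 0 (without replicate 2 or 3, by edgeR, where 2088 and 2273 genes had an unadjusted p below 0.05) to 2401 (without replicate 4) in whole libraries. They ranged from 6 (without replicate 1) to 812 (without replicate 3) in Sertoli-like cells, and from 39 to 314 (without replicate 4) in endothelial-like cells. In lymphocyte-like cells the range was 0 (without replicate 1, by edgeR, with 227 at an unadjusted p below 0.05) to 116 (without replicate 2 or 4). In mural-like, spermatogonium-like and stroma-like cells it was 9 (without replicate 2) to 439, 17 (without replicate 2) to 966 and 22 (without replicate 3) to 957, each highest without replicate 4. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.

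Camera with the estimated correlation called 0 lists in Sertoli-like cells (3 with the preset correlation), 0 in endothelial-like (3), 0 in lymphocyte-like (2), 0 in mural-like (2) and 0 in stroma-like cells (4). By library totals and the preset correlation, camera called 5 in stroma-like cells, with IGF and insulin added (adjusted p = 0.0336, with Benjamini-Hochberg adjustment), and as many as with TMM elsewhere. With 1 library left out, lists called ranged from 3 to 7 in Sertoli-like, 0 to 4 in endothelial-like, 0 to 3 in lymphocyte-like, 1 to 2 in mural-like, 0 to 0 in spermatogonium-like and 1 to 6 in stroma-like cells.

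Germ cells followed the same order of ages under the stricter filter, with shares of 4.88% and 3.44% at 6 months, 32.2% and 20.9% at 18 months, 72.5% at 4 years and 7.92% in the cattle-yak. With up to 40% mitochondrial UMIs they were 13.8% in replicate 3 and 34.2% at 4 years. Sertoli-like shares at 6 months were 30.1% and 31.4% with doublets kept, 34.9% and 27.0% under the stricter filter and 31.1% and 29.6% with up to 40% mitochondrial UMIs, and 0% at 4 years under the stricter filter. With up to 40% mitochondrial UMIs the Sertoli-like share of replicate 3 was 5.10%, against 2.34%. Under the stricter filter, spermatocyte-like shares of germ cells joined clusters 20 and 26. These shares were 4.60% in replicate 4, 61.5% at 4 years and 62.8% in the cattle-yak. At 4 years they were 38.7% with doublets kept, 50.3% at 2 times the resolution and 49.8% with up to 40% mitochondrial UMIs, where spermatid-like shares were 49.3%, 37.2% and 36.3%. With doublets kept, 1 of 126 germ cells of the cattle-yak was spermatid-like (0.794%, 0.0201–4.34).

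With a pseudocount of 10 CPM, 1 list lay outside the random range in mural-like cells at 4 years (0 with 1 CPM) and 1 in cluster 29 of the cattle-yak (2 with 1 CPM). Depth limited the rarer classes, and mural-like cells had 3441 genes to test against 9171 in stroma-like cells.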

Other observations

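The counts of shared genes, and the genes and clusters named in this part, were chosen after their values were seen.

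Cluster 29 held 312 cells of the cattle-yak (8.57%, 7.68–9.52) and 68 of the yak of 4 years. By the naming rule mural and lymphocyte markers were raised in it alike, though ACTA2, PTPRC and IL7R had 0 counts in the yak. Sertoli markers were present in both libraries, with INHA at 1167 CPM in the yak and 824 CPM in the cattle-yak, CITED1 at 694 and 503, CST3 at 8291 and 6015 and SOX9 at 135 and 111 CPM. DEFB123, WFDC2 and AARD led the cluster, at a median of 882 UMIs per cell. Against the yak of 4 years, collagen and matrix genes in it had a median log2 ratio of 3.12 (percentile 97.8), or 0.33 with members at 0 counts set at their bound, and stress genes 2.63 (percentile 100), or 1.94. DKKL1, a gene of sperm, was 56.8-fold lower in the cattle-yak (29.5–123), at 25.9 against 1472 CPM.

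Cluster 36 (134 cells, median 7494 UMIs) carried endothelial and mural markers alike, with CA4, HIGD1B and RGS5 leading. Cluster 38 led with SOX9, GRB14 and TEX15, had FSHR at 229 CPM in replicate 3, and held 76 cells of replicate 3 and 9 of replicate 4, at a median of 677 UMIs. Cluster 40 (24 cells) led with S100A4, SCN7A, CDH19 and L1CAM, genes of peripheral glia among them.

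Sertoli-like and spermatogonium-like cells shared 20 of their 77 and 188 genes called between 6 and 18 months, among 7167 tested in both, all in the same direction. Both classes come from the same 4 libraries, so a shift of a whole library would also give shared calls. Among them were the mitochondrial ND1, ND2, COX1 and CYTB and the endoplasmic reticulum gene KDELR3. Mural-like and stroma-like cells shared 8 of 39 and 21 among 3388, with ACTA2, MYH11, S100A4 and GALR1 among them. ENSBGRG00000010827 fell in all 6 tested classes, for example by 5.54 in Sertoli-like and 4.76 in spermatogonium-like cells (adjusted p = 0.0143 and 1.87e-09, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and in whole libraries had an adjusted p of 0.0632 (edgeR quasi-likelihood with Benjamini-Hochberg adjustment).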
